A study of Mus musculus with 4 samples.

How the data were processed

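The 4 libraries came from B16F10 tumours, a transplantable melanoma line of C57BL/6 mice. Per the labels' protocols, B16F10 cells in 50% Matrigel were injected into the skin of C57BL/6J mice, and doxycycline in the chow (200 mg/kg) switched on the hairpin. The tumours were digested with Collagenase I and DNase I, and cells were sorted on CD45 before PIP-seq, a droplet method that tags each molecule with a cell barcode and a unique molecular identifier (UMI). Groups were taken from the submitters' labels only: 2 hairpins (shNTC, a non-targeting control, and shHoxd13) by 2 CD45 fractions, with 1 library per group.

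The deposited values were whole-number UMI counts per gene and barcode, not normalized, for every barcode rather than for called cells. Per the submitters' processing notes, Seurat 5 and the mm10 genome build were used. The aligner and counting program were not given in the sources used here, and neither was the authors' choice of cells or cell types. The deposited counts covered 48443 genes in each library. Gene positions were read from the GENCODE vM21 annotation of the same build.

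The names of the deposited files put the hairpin arms the other way round from the labels. Groups followed the labels, and each direction is given as of the library labelled so.

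Cells were called per library from the deposited counts. A barcode needed UMIs at or over the larger of 500 and the 99th percentile of UMIs among the top 3000 barcodes divided by 10. It also needed at least 250 genes and at most 15% mitochondrial UMIs. The UMI minimum came to 3103 (labelled shNTC, CD45-negative), 5552 (shNTC, CD45-positive), 1708 (shHoxd13, CD45-negative) and 1406 (shHoxd13, CD45-positive). The mitochondrial ceiling then removed 273, 541, 4 and 100 barcodes in the same order. Scrublet, a doublet caller, marked 0.0188%, 0.0404%, 0.168% and 0.0931% of cells, all under the preset 0.5%, so its calls were not used and no doublet was removed. Doublets therefore stayed in the data, and an alternative without the 5% of cells with the highest Scrublet scores was run.

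All 4 libraries were clustered together with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1). Lymphoid and myeloid clusters were then clustered again within their lineage, as was each other cluster under 200 cells, and no batch correction was applied. A cluster was named for the class with the highest marker score, from markers fixed in advance, where at least 3 were detected. Detected meant 20 CPM or more and 2-fold over the lower quartile of clusters plus 10 CPM. The 10 leading genes of a cluster were read against its name. The scoring rule behind the names was settled after the clusters had been seen, with the markers unchanged, and 3 rules were tried. It left 55 cells led by Cd207, a Langerhans cell gene, unnamed. They made up 1.15% of the library labelled shHoxd13 CD45-negative and 0 cells elsewhere.

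UMIs were summed per class and library and given as CPM, the gene's UMIs relative to all UMIs of that class and library. A class was compared where both libraries held at least 30 of its cells, and a gene counted as measured at 50 UMIs or more over both. Genes at 0 UMIs in one library were left out of the measured set where its floor of 3 counts lay over the other library's CPM. That filter was added after the values had been seen. CPM carry exact Poisson intervals, shares of cells exact Clopper-Pearson intervals, and ratios exact conditional binomial intervals, all at 95%. These intervals, and the floor of 3 counts used where a count was 0, cover counting error only.

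Each preset gene list is given as the median log2 CPM ratio of its measured members, with an interval from 1000 Poisson redraws. Its percentile is that among 10000 random lists of the same size matched on mean expression, which describes these libraries and is no test. Members 1.5-fold or more apart were counted per direction. The lists named here are MHC class I and II presentation, interferon response, chemokines, cell cycle, dissociation stress and the adenosine pathway, and in fibroblast-like cells also hypoxia and glycolysis, TGF-beta response, angiogenic ligands, anti-angiogenic factors and checkpoint ligands.

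Genes were named by a fixed rule. Per class these were the 10 highest and 10 lowest ratios whose interval excluded 1.5-fold, without mitochondrial genes, ribosomal protein genes and models named by number. The CPM in the higher library had to come near the gene's highest CPM over that library's classes (at least that value divided by 3), so that free RNA was not named. The rule added the 2 highest and 2 lowest members of each list, and Hoxd13, Ptprc, Vegfa, Sema3a and Nt5e wherever measured. A gene picked by the rule in fibroblast-like cells is not reported here. Groups, markers, lists and this rule were fixed before the data were examined. So were most alternatives for Hoxd13 and for the planned class shares, but not those for other values.

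The ratio calculation was tested on simulated counts in which 200 genes had been changed. Both libraries were drawn as Poisson counts from the same pooled profile. The share of intervals holding 1 was therefore set by the design, and variation between cells and libraries was left out. For the keratinocyte-like comparison (11763 genes), 96.4% of unchanged genes had an interval holding 1. Of genes changed 2-fold, 47.2% were recovered, and of those changed 4-fold, 95.7%. For the fibroblast-like comparison (18942 genes before the filter on genes at 0 UMIs, which the tested genes passed), the values were 96.6%, 32.5% and 69.6%.

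Shares of cells with a UMI were also computed after thinning every cell to 500 UMIs. No called cell was shallower than that. Alternatives changed the cell calling, mitochondrial ceiling, doublets, cluster resolution, clustering by fraction, scaling, free RNA, weighting of cells, low-count filter, reference library and fraction labels. With 1 library per group there was no test between groups, and no p-value or count of changed genes is given. Software versions were python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.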

Results

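Single-cell RNA counts were available for 4 libraries of B16F10 melanoma tumours grown in mouse skin, with 1 library for each of 2 hairpins and 2 CD45 fractions. The design compared tumours carrying a hairpin against Hoxd13, a homeobox transcription factor, with control tumours (shNTC), and the series title named angiogenesis and immune evasion as its subjects. The library labelled shNTC CD45-negative held 144055532 UMIs and gave 10631 called cells, with a median of 11058 UMIs per cell. The one labelled shNTC CD45-positive held 273825729 UMIs and gave 9909 cells (median 19512). The library labelled shHoxd13 CD45-negative held 35567981 UMIs and gave 4764 cells (median 4797), and the one labelled shHoxd13 CD45-positive 20443042 UMIs and 3224 cells (median 4325.5). Called cells took 87.9%, 75.8%, 75.3% and 77.7% of each library's UMIs in that order. No group had a replicate, so every difference given here lies between single libraries. The data went against the fraction labels of both libraries labelled shHoxd13 and against the CD45-positive label of the one labelled shNTC, which held 2 cells of immune classes among 9909 (0.0202%), and the names of the deposited files put the 2 arms the other way round, which bears on every direction given.

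Hoxd13 (ENSMUSG00000001819, chromosome 2, 74668310 to 74671599, plus strand of mm10) was found at a low level in the libraries labelled shNTC and in no called cell of those labelled shHoxd13. It reached 0.324 CPM (41 UMIs, 95% interval 0.232 to 0.439) in the library labelled shNTC CD45-negative and 0.327 CPM (68 UMIs, 0.254 to 0.415) in the one labelled shNTC CD45-positive. Both libraries labelled shHoxd13 had 0 UMIs in called cells, where 3 counts would be 0.112 CPM (CD45-negative) and 0.189 CPM (CD45-positive). Against those floors Hoxd13 was 2.89-fold lower in the library labelled shHoxd13 CD45-negative and 1.73-fold lower in the CD45-positive one. These folds leave out counting error, since 0 UMIs allow up to 0.138 and 0.232 CPM there. Over all barcodes the 4 libraries held 47, 89, 3 and 0 Hoxd13 UMIs.

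All 41 and 68 Hoxd13 UMIs lay in fibroblast-like cells, and the libraries labelled shHoxd13 held 2 and 67 such cells, so the gap between arms went with the cell types captured. The 67 fibroblast-like cells had 0 Hoxd13 UMIs with a floor of 3.32 CPM, above the level in the other arm. The 35 melanoma-like cells of the library labelled shHoxd13 CD45-positive also had 0, with a floor of 35.8 CPM, and the libraries labelled shNTC held 1 melanoma-like cell. A knockdown of Hoxd13 in melanoma-like cells was not detectable at this depth. The direction of the arms could not be checked from this gene. The melanoma-like class was named from melanocyte genes such as Dct and Pmel. Whether its cells were tumour cells was not tested.

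Ptprc (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708, minus strand), which encodes the sorting antigen CD45, was high in 1 library only, the one labelled shHoxd13 CD45-negative. There it stood at 942 CPM (931 to 954), and 94.1% of cells (93.4 to 94.7) had a Ptprc UMI. In the library labelled shHoxd13 CD45-positive it stood at 2.46 CPM, with 0.310% of cells (0.149 to 0.570). The libraries labelled shNTC CD45-negative and CD45-positive had 0.260 and 0.539 CPM, with a Ptprc UMI in 0.216% (0.137 to 0.324) and 0.928% (0.749 to 1.14) of cells. After thinning to 500 UMIs the shares were 37.8% (shHoxd13, CD45-negative), 0.186% (shHoxd13, CD45-positive), 0.00941% (shNTC, CD45-negative) and 0.0101% (shNTC, CD45-positive), the last 2 being 1 cell each.

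Within the library labelled shHoxd13 CD45-negative, Ptprc was found in 97.3% of CD8 T-like, 98.7% of NK-like and 89.0% of macrophage-like cells (median 4351, 3491.5 and 7239 UMIs). Keratinocyte-like cells, which should lack it, gave the background, 3 of 22 cells or 13.6% (2.91 to 34.9) at a median of 6653 UMIs, and 0 after thinning. Keratinocyte-like cells of the library labelled shHoxd13 CD45-positive had a share of 0.0988% (3 of 3037). Col3a1, a fibrillar collagen, stood at 2508 and 2328 CPM in the libraries labelled shNTC, against 15.2 (shHoxd13, CD45-negative) and 391 CPM (shHoxd13, CD45-positive). Krt14, a keratin of basal epidermis, reached 3246 CPM in the library labelled shHoxd13 CD45-positive, against 58.0, 52.3 and 19.2 CPM in the others. Dct (ENSMUSG00000022129, chromosome 14, 118012790 to 118052244, minus strand), a melanin synthesis enzyme, stood at 0.0710 and 0.207 CPM in the libraries labelled shNTC, at 2.28 CPM in shHoxd13 CD45-negative and at 40.7 CPM in shHoxd13 CD45-positive.

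**Figure D1:**
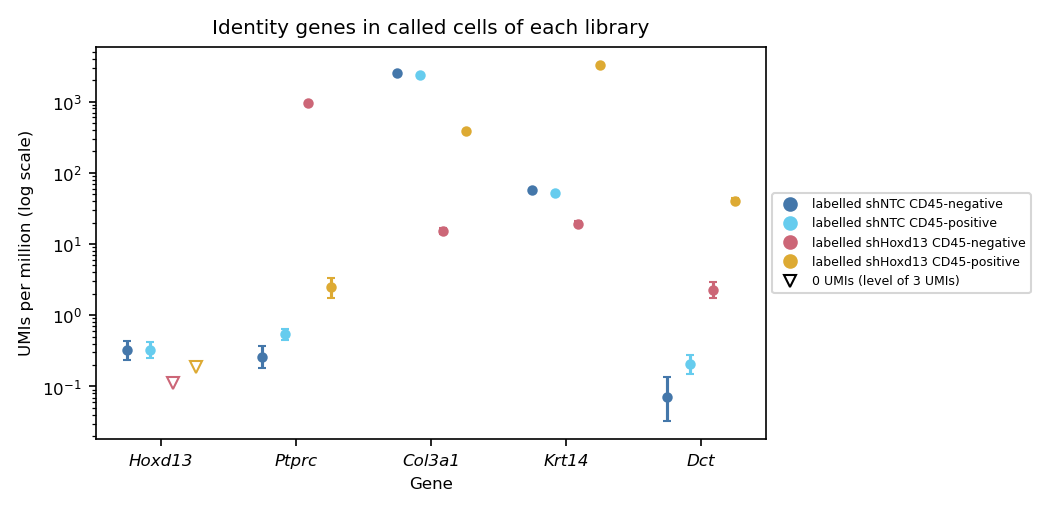
Level of Hoxd13, Ptprc, Col3a1, Krt14 and Dct in called cells of each library, in CPM on a log axis, with 1 point per library, 95% Poisson bars and triangles at the level of 3 UMIs where the count was 0. Ptprc stood at 942 CPM in the library labelled shHoxd13 CD45-negative and at 2.46 CPM or less in the other 3 libraries.

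The 2 libraries labelled shNTC shared most of their cell barcodes. Of their called cells, 9294 had the same barcode in both, 93.8% of the smaller library, where 51.4 would be shared by chance. The other 5 pairs of libraries shared 0 called barcodes, with 11.2 to 25.1 from chance. The chance level, from random draws of barcodes, was thus too high for those pairs and is only rough. Over 1000 shared barcodes, the expression profiles of the same barcode had a median Pearson r across genes of 0.815, against 0.416 for different barcodes, with genes not being independent replicates. Of the shared barcodes, 99.9% fell in the same class in both libraries. These libraries were therefore not treated as separate samples of each other, and comparisons with either of them rest largely on the same cells.

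In the libraries labelled CD45-negative, the one labelled shHoxd13 held immune cells and the one labelled shNTC fibroblast-like cells. Immune classes made up 98.2% (97.8 to 98.6) of the cells labelled shHoxd13. CD8 T-like cells were 40.1% (38.7 to 41.5), macrophage-like 25.7% (24.4 to 26.9), NK-like 8.27% and gamma delta T-like 8.10%. Naming thinned cells by their own marker UMIs gave lower CD8 T-like and macrophage-like shares, beyond these intervals, as given with the alternatives. Smaller classes there were T-like (3.93%), cDC2-like (conventional dendritic, 3.65%), monocyte-like (2.23%) and regulatory T-like (1.83%) cells. The T-like class was cluster L05, whose 10 leading genes included Klra1, Klra6 and the NK marker Klra7. In the library labelled shNTC CD45-negative, 98.6% (98.4 to 98.8) of cells were fibroblast-like and 0.875% keratinocyte-like. Hmga2 was among the 10 leading genes of most fibroblast-like clusters, and Col3a1 of fewer. Clusters such as 02, 05, 15 and 20 had 0 fibroblast markers among theirs. Their marker scores were 2.38, 2.25, 1.72 and 2.00, against 7.17 for the fibroblast-like cluster 23s1, so the name is weak there. Sema3a, a repulsive guidance cue for vessels and axons, stood at 231 CPM in the library labelled shNTC and 1.27 CPM in the one labelled shHoxd13, and Vegfa, the main angiogenic growth factor, at 67.6 and 151 CPM. Nt5e, the ectoenzyme that makes adenosine from AMP, stood at 103 and 22.8 CPM. These gaps lie between mixtures of different cell types.

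Endothelial-like cells, the class tied to the angiogenesis question, were 3 of 4764 cells (0.0630%, 0.0130 to 0.184) in the library labelled shHoxd13 CD45-negative and 14 of 10631 (0.132%, 0.0720 to 0.221) in the one labelled shNTC. The ratio of the 2 shares was 0.478 (0.0881 to 1.71), so a difference was not detectable between the libraries so labelled. Leiden resolution 0.5 gave no endothelial-like cells in either library. Clustering each fraction on its own raised the share labelled shNTC. With the fraction labels of the pair labelled shHoxd13 exchanged, a setting chosen after seeing the data, the share was 60 of 3224 cells (1.86%, 1.42 to 2.39) against the same 14 of 10631, a ratio of 14.1 (7.80 to 27.4). The result thus depends on the fraction labels. Immune classes made up 98.2% of the library labelled shHoxd13 CD45-negative, so its endothelial-like share does not describe a fraction cleared of immune cells. The ratio of 0.478 therefore does not bear on angiogenesis, and the shares are set by the sort as well as by the tissue. No class had 30 cells in both libraries, and the planned melanoma-like and endothelial-like gene lists gave no value.

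**Figure D2:**
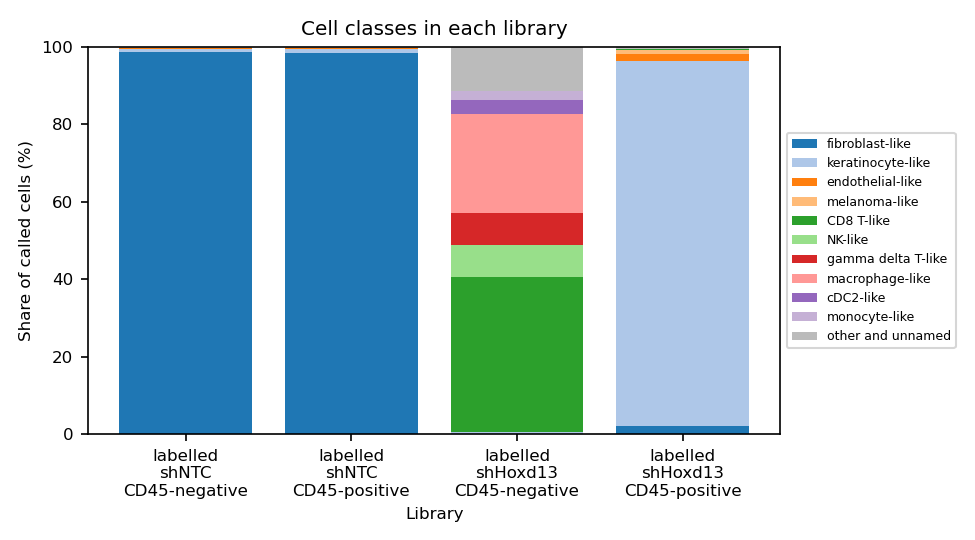
Share of called cells in each cell class, in percent, as 1 stacked bar per library in the order of the labels. The library labelled shHoxd13 CD45-negative was 98.2% immune, that labelled shHoxd13 CD45-positive 94.2% keratinocyte-like, and both labelled shNTC 98.6% fibroblast-like.

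In the libraries labelled CD45-positive, immune cells were almost absent from both arms. The library labelled shHoxd13 held 94.2% (93.3 to 94.98) keratinocyte-like, 2.08% fibroblast-like, 1.86% endothelial-like and 1.09% melanoma-like cells, and the one labelled shNTC 98.6% fibroblast-like, 0.979% keratinocyte-like and 0.151% endothelial-like cells. The melanoma-like cluster was led by Dct and Pmel but also by the immunoglobulin genes Igkc and Jchain. CD8 T-like cells were 5 of 3224 (0.155%, 0.0504 to 0.362) in the library labelled shHoxd13 and 0 of 9909 (interval up to 0.0372%) in that labelled shNTC, where a floor of 3 cells would be 0.0303%. Against that floor the share of 5 cells was at least 5.12-fold higher in the library labelled shHoxd13, without the counting error of the 5 cells. Macrophage-like cells were 0 of 3224 (interval up to 0.114%) and 2 of 9909 (0.0202%, 0.00244 to 0.0729), both under the floor, so no ratio is given. Naming thinned cells by their own marker UMIs gave a higher macrophage-like share in the library labelled shHoxd13, as given with the alternatives. Only 0.310% of its called cells had a Ptprc UMI, and together they held 13 UMIs of the macrophage marker Csf1r. That higher share therefore does not show macrophages. Immune classes together were 0.217% (0.0873 to 0.447) of the library labelled shHoxd13. The planned CD8 T-like and macrophage-like gene lists gave no value. The 5 CD8 T-like cells were 0 when each fraction was clustered on its own.

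Keratinocyte-like cells, 1 of the 2 classes with enough cells in both arms, had lower cell cycle and higher dissociation stress list medians in the library labelled shHoxd13 CD45-positive (3037 cells) than in that labelled shNTC CD45-positive (97 cells). Of 26 measured cell cycle genes, 24 were 1.5-fold or more lower and 0 higher in the library labelled shHoxd13, with a median log2 ratio, labelled shHoxd13 over labelled shNTC, of -2.86 (-2.95 to -2.64, percentile 0 among random lists). Of 20 dissociation stress genes, 15 were higher and 3 lower, with a median of 1.45 (1.40 to 1.52, percentile 100). The labels fix none of these directions, since the names of the deposited files put the arms the other way round. The median over all 11763 measured genes was -0.05.

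Among cell cycle genes, Cdc20, an activator of the anaphase-promoting complex, stood at 4.84 CPM in the library labelled shHoxd13 against 78.7 CPM (log2 ratio -4.02, -4.48 to -3.57). Aurkb, a mitotic kinase, had a log2 ratio of -3.83 (-4.70 to -2.97). The replication genes Mcm6 and Pcna were closest to parity among the list's members, at -0.51 (-0.92 to -0.08) and -0.23 (-0.52 to 0.07). Cep55, needed for the final step of cell division, had a log2 ratio of -4.09, and the linker histone gene Hist1h1b one of -3.96. Among stress genes, Zfp36, an mRNA decay factor, stood at 1342 against 237 CPM (log2 interval 2.34 to 2.67). Socs3, a feedback inhibitor of cytokine signalling, stood at 469 against 115 CPM (2.03). The heat-shock genes Hspa1b and Hspa1a went the other way, with log2 ratios of -1.17 and -1.03.

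Lists of antigen presentation and inflammatory genes had medians under 0 in the keratinocyte-like cells labelled shHoxd13, with most MHC class I members under 1.5-fold and chemokine and interferon genes going both ways. The MHC class II list had a median log2 ratio of -0.97 (-1.41 to -0.76, percentile 0.130), with 4 of 6 measured members lower and 0 higher. Against the cells labelled shNTC CD45-negative, a reference added after seeing the data, its median was -2.13. Both libraries labelled shNTC held largely the same cells, but this reference summed 645343 UMIs against 1295675, and its measured genes were chosen anew. Such moves may come from the library, from other measured members or from counting error in the shallower sum, which were not told apart. The interval of the main value does not cover them. H2-Aa, an MHC class II chain, stood at 8.10 against 35.5 CPM (-2.13) and Cd74, the invariant chain, at 20.5 against 81.0 CPM (-1.98), while H2-DMb1 and H2-DMa had -0.55 and -0.53. The MHC class I list had -0.25 (-0.40 to -0.11, percentile 2.58), with 6 of 20 members lower and 0 higher, from Erap1, a peptide-trimming enzyme, at -1.01 to the transactivator gene Nlrc5 at 0.35. The tapasin gene Tapbp stood at 55.8 against 112 CPM, and H2-Q4 had a log2 ratio of 0.23. Of 10 measured chemokine genes, 6 were lower and 1 higher (median -0.81, -1.06 to -0.27, percentile 0.180), and with at least 200 UMIs per gene the chemokine median turned to 0.26. Ccl8 stood at 1 UMI against 103 (log2 ratio -10.17, -15.48 to -7.66), and Cxcl9, an interferon-induced T cell attractant, at 10.7 against 53.3 CPM (-2.31). Cxcl12 and Ccl20 had 0.36 and 1.34. Of 22 interferon response genes, 10 were lower and 4 higher (median -0.33, -0.66 to -0.04, percentile 7.38), with Gbp2 at -2.04, Irf1 at 1.09 and Ifit1 at 1.41.

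The adenosine list, tied to Nt5e, had a median of -0.04 (-0.25 to 0.21, percentile 61.1), with 1 of 9 members higher and 2 lower. Dpp4 and Slc29a2 had log2 ratios of -1.60 and -1.55, and Enpp1 and the receptor gene Adora2b 0.16 and 0.97. Nt5e itself stood at 37.7 against 34.0 CPM (0.15, -0.29 to 0.63), and Vegfa at 29.0 against 37.8 CPM (-0.38, -0.81 to 0.07), so neither differed beyond counting error.

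Among the lowest single ratios outside the lists, Krt6b, a keratin of wounded or hyperproliferative epidermis, stood at 0.415 against 128 CPM (log2 ratio -8.27), the glutathione transferase gene Gsta4 at 1.59 against 88.0 CPM (-5.79) and Lcn2, an iron-sequestering protein of inflamed epithelium, at 1.66 against 29.3 CPM (-4.14). The protease gene Tmprss11g had -5.18, and Sprr2a2, which encodes a cornified envelope protein and also leads a cluster, -4.43. At the other end, Skint7, a skin gene of the Skint family, stood at 37.4 CPM against 0.772 CPM (5.60, 3.12 to 10.91), and Cdsn, which encodes corneodesmosin, at 18.5 CPM (4.59, 2.10 to 9.90). Tacr3 (4.19), Matn4 (3.97), Fgf18 (3.96), Far2 (3.92), Nell1 (3.90), Mn1 (12.1-fold), Cbx2 (3.52) and Cdh23 (3.46, 1.90 to 5.75) followed, all of them at 1 to 3 UMIs in the library labelled shNTC. Against the keratinocyte-like cells labelled shNTC CD45-negative, Cbx2, Far2, Matn4 and Cdsn had 0.93, 1.33, 1.38 and 2.00. These values put that reference at 3 counts (4.65 CPM), the floor used for a count of 0, so they do not show smaller differences. The other list medians against that reference included -1.40 for chemokines, -0.97 for interferon response and -0.72 for MHC class I. Without the mitochondrial ceiling Fgf18 had 1.52 and Far2 0.97.

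These cells differed in depth, clusters and fibroblast RNA as well. Their median was 4301 UMIs in the library labelled shHoxd13 and 12566 in that labelled shNTC. Cluster 08 held 41.9% and 36.1% of them, cluster 13 23.8% and 40.2%, cluster 22 7.77% and 18.6%, cluster 19 12.9% and 5.15%, and cluster 18 13.6% and 0%. Dcn, a fibroblast proteoglycan, stood at 7.34 and 86.4 CPM, Col3a1 at 7.96 and 57.1 CPM and Hmga2 at 2.84 and 16.2 CPM. In the fibroblast-like cells labelled shNTC CD45-positive, Hmga2 reached 798 CPM and Cdc20 62.8 CPM.

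Fibroblast-like cells of the library labelled shHoxd13 CD45-positive (67 cells) had median log2 ratios under 0 for the interferon, MHC class I and hypoxia lists against those labelled shNTC CD45-positive (9768 cells), with some members of each list less than 1.5-fold apart. Of 29 measured interferon response genes, 27 were 1.5-fold or more lower and 0 higher, with a median log2 ratio of -1.73 (-1.91 to -1.58, percentile 0). Of 22 hypoxia and glycolysis genes 14 were lower and 0 higher (-0.77, -0.86 to -0.63, percentile 0), and of 20 MHC class I genes 10 were lower and 0 higher (-0.59, -0.73 to -0.44, percentile 0). The median over all 15434 measured genes was 0.14, so these medians lie further from the typical gene than from 0. The arms are again those of the labels, with the names of the deposited files the other way round.

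The class was made of different clusters in the 2 libraries. Cluster 23s1 held 35 of the 67 cells (52.2%, 39.7 to 64.6) in the library labelled shHoxd13 and 1 of 9768 in that labelled shNTC, whose cells were spread over clusters 00 (13.8%), 01 (12.2%), 02 (11.7%), 03 (11.02%) and others. Values without cluster 23s1, a setting chosen after seeing the data, compare the remaining 32 cells. There the interferon list had -1.90, the MHC class I list -0.59 and the hypoxia and glycolysis list -0.37.

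Mx1, an antiviral gene of the interferon list, had 0 UMIs in the cells labelled shHoxd13 against 34.9 CPM. With the floor of 3 counts it was 10.5-fold lower, and its log2 interval reached up to -3.10. Cxcl10, an interferon-induced chemokine, stood at 84.0 against 715 CPM (-3.09, -3.43 to -2.76), and Socs1 and Cxcl9 at -0.58 and -0.35. In the hypoxia list Ankrd37 (2 UMIs) had -3.68 (-6.73 to -1.83) and Ddit4, a stress-induced inhibitor of mTOR signalling, -2.49, while the glycolytic gene Pfkp and Ndrg1 had 0.07 and 0.18. In the MHC class I list the non-classical H2-T23 had -2.20 and the immunoproteasome gene Psmb9 -1.83, and the chaperone genes Calr and Canx 0.34 and 0.40. The MHC class II list had a median of 2.37 (1.27 to 3.28, percentile 99.9) with 4 of 6 members higher and 2 lower, and of 3.96 at Leiden resolution 0.5. It rests on few UMIs, such as 12 for H2-Ab1 (5.37, 4.35 to 6.27), 6 for H2-Aa (4.66), 2 for Ctss (-0.66, -3.71 to 1.19) and 1 for Cd74 (-0.65, -5.96 to 1.83).

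Among angiogenic ligands, 8 of 21 measured genes were higher and 5 lower, with a median of -0.04 (-0.28 to 0.21, percentile 22.1). Cxcl12, a chemokine for endothelial and blood cells, stood at 614 against 93.7 CPM (2.71) and Adm, the vessel-dilating peptide adrenomedullin, had 3.85. Hgf had -2.25, and Spp1, osteopontin, which also leads a cluster, -2.19. The list stood at -0.29 without cluster 23s1 and at 0.66 at Leiden resolution 0.5. Vegfa stood at 53.1 against 68.3 CPM (-0.36, -0.81 to 0.04). Sema3a stood at 208 against 277 CPM (-0.42, -0.63 to -0.21) and at 0.14 without cluster 23s1. Anti-angiogenic factors had a median of 0.30 (0.06 to 0.38, percentile 96.2), with 7 of 14 higher and 3 lower, and -0.45 without cluster 23s1. Sema3b had 2.46 and the collagen gene Col4a3 3.77, and Isg15 -2.57.

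Immune-related lists went both ways in fibroblast-like cells. The adenosine list had a median of 0.14 (-0.48 to 0.49, percentile 47.0), with 4 of 11 higher and 4 lower. It moved to -0.74 where at least 10 UMIs were expected in the shallower library. Nt5e stood at 18.8 against 113 CPM (-2.59, -3.37 to -1.91), at -3.45 without cluster 23s1, at -3.86 without the highest Scrublet scores and at -1.90 with the mean of per-cell CPM. Enpp1 had -1.79, Cd38 (3 UMIs) 1.59 (-0.70 to 3.15) and Dpp4, a surface peptidase, 5.72. Of 10 checkpoint ligand genes 4 were higher and 3 lower (-0.08, -0.41 to 0.48, percentile 14.1). Cd274, which encodes PD-L1, had -2.58 (-4.21 to -1.36) and Pvr -1.24, against 1.43 for Cd276 and 2.43 for Cd80. Chemokines had -0.27 (-0.38 to -0.12, percentile 1.97), with 4 of 14 higher and 3 lower, among them the monocyte attractant Ccl2 at 174 against 618 CPM (-1.83) and Cxcl16 at 2.83.

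The TGF-beta response list had -0.15 (-0.26 to 0.06, percentile 7.48), with 3 of 19 higher and 6 lower. The targets Id3 and Id1 had -1.31 and -1.28, and the matrix genes Ltbp2 and Col1a1, the latter also leading clusters, 2.98 and 2.86. Cell cycle genes had 0.01 (-0.15 to 0.14, percentile 35.4), with 4 of 28 higher and 4 lower. Rrm2, which also leads a cluster, and Aurka had -0.96 and -0.63, and Mcm5 and Ccne2 both 0.91. Dissociation stress genes had 0.05 (-0.04 to 0.09, percentile 64.6), with 1 of 20 higher and 5 lower, from Hspa1b (-2.90) and Hspa1a (-2.20) to Atf3 (0.31) and Jund (1.06). Without cluster 23s1 the stress list had -1.01, the cell cycle list 0.58, the TGF-beta list -0.56 and the checkpoint list -0.59. Other settings moved some of these the other way: Leiden resolution 0.5 gave -0.57 for the cell cycle list and 1.40 for the checkpoint list, and at least 1000 UMIs per cell gave 0.48 for the checkpoint list.

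The highest single ratios were Gdf10, a ligand of the BMP family, at 90.7 against 0.0486 CPM (10.87, 9.91 to 11.98), and Clec3b, which encodes tetranectin, at 216 against 0.117 CPM (10.85). Gas6, the ligand of the Axl receptor family, followed at 446 against 0.350 CPM (10.31), then the ectonucleotidase gene Entpd2 (9.81), Lbp (9.27), Igfbp5 (8.98) and the cell cycle inhibitor gene Cdkn1c (8.96). Adamts15 had 8.83, Tnxb, tenascin X, 8.53, and Gpx3, which also leads cluster 23s1, 8.42. Most of their UMIs came from cluster 23s1. Without it Gdf10 had 0 UMIs, and the intervals of Tnxb (1.38, -3.94 to 3.88) and Cdkn1c (4.02, -1.35 to 6.65), each at 1 UMI, held parity. Gpx3 had 3.64, Gas6 4.48, Entpd2 5.15 (2.01 to 7.20), Lbp 5.52, Igfbp5 5.53, Clec3b 6.27 and Adamts15 7.06. Of these, Entpd2 rested on 2 UMIs, Gas6 and Lbp on 4 each, Clec3b on 5 and Adamts15 on 6. Against the fibroblast-like cells labelled shNTC CD45-negative, Gdf10 had 13.48 and Gpx3 7.27.

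The lowest single ratios rested on 1 or 2 UMIs in the cells labelled shHoxd13. Mmp13, a collagenase that also leads a cluster, stood at 1.11 against 395 CPM (-8.48, -13.79 to -6.00) and at -5.24 with the mean of per-cell CPM, and the related protease gene Mmp10 had -5.53 (-10.83 to -3.05). The cannabinoid receptor gene Cnr1, another cluster leader, had -5.57, the phosphatase gene Ptpn22 -5.39, Upk1b -4.76 and the histone gene Hist1h4d -4.60. The ubiquitin ligase gene Rnf128 had -3.88, the cytokine gene Tslp -3.87 (-6.92 to -2.02) and Mir670hg -3.83. Without cluster 23s1 these ran from -7.84 (Mmp13) to -3.18 (Mir670hg).

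Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847, plus strand), a translation factor gene expressed widely in male cells, was lower in fibroblast-like cells outside cluster 23s1 than in keratinocyte-like cells of the same libraries. It was singled out after its values were seen. It stood at 0.183 CPM (0.116 to 0.275) and 0.190 CPM (0.135 to 0.259) in the fibroblast-like cells labelled shNTC CD45-negative and CD45-positive, but at 57.3 and 73.3 CPM in the keratinocyte-like cells of the same libraries. The 24 skeletal muscle-like cells labelled shNTC CD45-negative had 0 UMIs, which allows up to 34.5 CPM. In cluster 23s1 of the library labelled shHoxd13 CD45-positive it reached 85.8 CPM (57.0 to 124), and in the other 32 fibroblast-like cells there 3.46 CPM (2 UMIs, 0.419 to 12.5). Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629, minus strand), a helicase gene of the same chromosome, stood at 157 and 168 CPM in the fibroblast-like cells labelled shNTC, at 245 CPM in cluster 23s1 and at 166 CPM outside it.

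**Figure D3:**
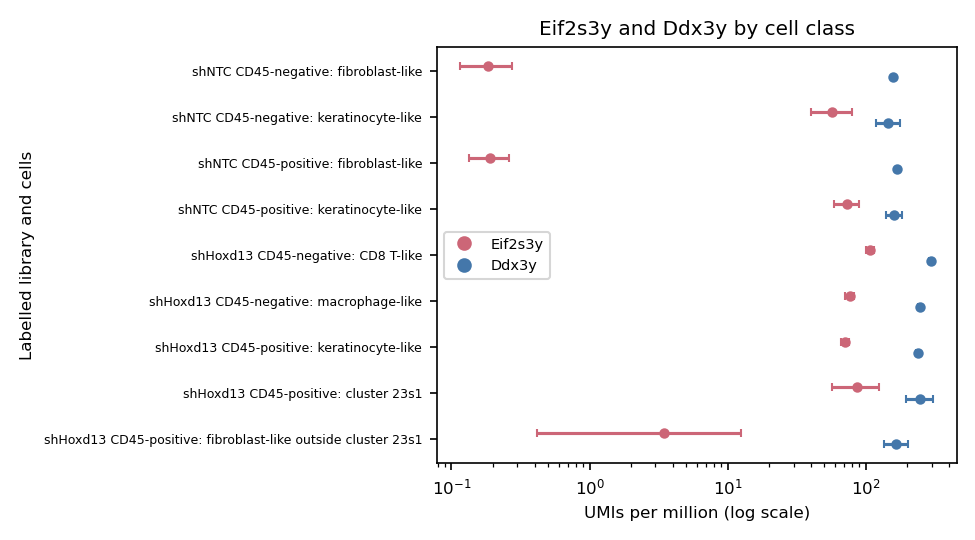
Level of the chromosome Y genes Eif2s3y and Ddx3y by cell class and library, in CPM on a log axis, with 95% Poisson bars. Eif2s3y stood at 0.183 and 0.190 CPM in fibroblast-like cells labelled shNTC, where Ddx3y stood at 157 and 168 CPM.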

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

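All of the tests in this part were chosen only after the result they weigh had been seen.

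The 2 libraries labelled shNTC shared far more cell barcodes than chance gives, although their labels name separate CD45 fractions. Chance reuse of barcodes is argued against, since 100% of the 1000 barcodes compared had their own partner as the best-matching profile. A small carry-over from one library would leave very unequal UMIs per barcode, but the median ratio was 1.84, and 1 set of counts at 2 depths would leave equal gene levels, but 5.72% of genes with 1000 UMIs or more differed 1.5-fold or more. The ratio between the libraries went with gene span (Spearman rho 0.444 across genes, which are not independent replicates). Genes spanning 9.90 kb or less had a median log2 ratio, CD45-positive over CD45-negative label, of -0.148, and those over 60.2 kb 0.205. Both medians lie under 1.5-fold. Among the genes furthest apart, Fhit (1612 kb, 1.91) and Hist1h2an (0.393 kb, -1.20) went with span. Ppfia2 (466 kb, -1.53) and Trim43c (9.03 kb, 6.37) went against it. Thus 1 pool of cells made into libraries that count long genes differently may account for part of how the libraries differ. It does not account for genes such as Ppfia2 and Trim43c. A CD45-positive fraction as the source of that pool is argued against, since immune classes made up 0.0188% (0.00228 to 0.0679) and 0.0202% (0.00244 to 0.0729) of the libraries labelled shNTC CD45-negative and CD45-positive. No biological explanation was tested.

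The CPM ratio of Ptprc, CD45-positive over CD45-negative label, was 0.00261 in the pair labelled shHoxd13 and 2.07 in the pair labelled shNTC. The difference between these ratios was not tested. The ratio labelled shNTC compares largely the same cells, at 0.539 and 0.260 CPM, so it places Ptprc on neither side of a sort.

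Free RNA as the source of Ptprc in the library labelled shHoxd13 CD45-negative is argued against, since its keratinocyte-like cells held 0.0188 times (0.00387 to 0.0549) the Ptprc CPM of its CD8 T-like cells. A first version of that test compared called cells (942 CPM) with barcodes of 10 to 100 UMIs (1325 CPM) and would have pointed to free RNA, but it was replaced because such barcodes of an immune library carry immune RNA themselves. Immune classes made up 98.2% of the library labelled CD45-negative and 0.217% of the one labelled CD45-positive, which is consistent with exchanged fraction labels in that pair. An exchange of the arm labels cannot be told apart from correct arms, since the libraries labelled shNTC held 1 melanoma-like cell in which Hoxd13 could be read. An effect of the hairpin on the tumour with the fraction labels right is argued against as the cause of this reversal, since a CD45-negative sort leaves out immune cells whatever the tumour holds, but immune classes, named from markers other than Ptprc, made up 98.2% (97.8 to 98.6) of the library so labelled. Whether the hairpin changed the shares within either fraction stays open and untested.

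Eif2s3y was nearly undetected in fibroblast-like cells of the libraries labelled shNTC while Ddx3y, also on chromosome Y, was not. Low detection of Eif2s3y in those libraries is argued against, since keratinocyte-like cells labelled shNTC CD45-negative held 313 times (181 to 552) the level of the fibroblast-like ones. A general lack of Eif2s3y in fibroblasts is argued against by cluster 23s1, at 85.8 CPM. Outside that cluster, fibroblast-like cells labelled shHoxd13 CD45-positive stood at 3.46 CPM (0.419 to 12.5), so a hypothesis is that these cells may share an origin other than that of the neighbouring skin cells. Dct stood at 0.0716 and 0.204 CPM in the fibroblast-like cells labelled shNTC, and whether they descend from the injected line was not tested.

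Dct, a melanocyte gene, stood out in barcodes too shallow to be called as cells: those with 10 to 100 UMIs held 204 CPM in the library labelled shHoxd13 CD45-negative and 158 CPM in that labelled shHoxd13 CD45-positive, against 0.107 and 0.393 CPM in the libraries labelled shNTC CD45-negative and CD45-positive. Barcodes under 10 UMIs held 901 CPM (shHoxd13, CD45-negative) and 332 CPM (shHoxd13, CD45-positive). In the library labelled shHoxd13 CD45-negative, uncalled barcodes with over 500 UMIs held 4.09 CPM and called cells 2.28 CPM. Uncalled barcodes of the library labelled shHoxd13 CD45-positive with over 500 UMIs but under its calling minimum held 413 CPM (366 to 465), against 40.7 CPM in its called cells. Whether melanoma cells lie among them was not tested on these barcodes alone. With at least 500 UMIs that library still had 35 melanoma-like cells, and with at least 1000 UMIs 28.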

How the results depend on the processing

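The tests chosen only after the data were seen are the alternatives for the gene lists, for single genes other than Hoxd13, for the Ptprc share and for the class shares outside the planned 3. They also include the removal of the highest Scrublet scores, the 10-UMI expectation, the other reference library, the removal of cluster 23s1 and the exchange of fraction labels. No paired analysis was possible because each group was 1 library. The planned melanoma-like, endothelial-like, CD8 T-like and macrophage-like gene lists gave no value under any alternative. Over all alternatives, 202 values that answer a comparison stayed within their counting interval and 41 left it. For single genes and other lists 795 stayed, 63 left it and 5 turned direction. All 5 had a main interval that excluded parity. Lists that changed sign and left a main interval holding parity, such as the adenosine list in fibroblast-like cells, were counted among the 63. The cause of these moves was not tested unless the setting itself shows it. Keeping doublets removed no cell and so says nothing, but its 21 and 58 values are counted among the 202 and 795 that stayed. Leiden resolution 2, free RNA subtraction, no mitochondrial ceiling and a 20-UMI filter left every value that answers a comparison within its interval. The free RNA subtraction took at most 100 UMIs from a cell, so it could move little. Keratinocyte-like cells compared there had medians of 4301 and 12566 UMIs. Without the ceiling the single genes Fgf18 and Far2 in keratinocyte-like cells moved to 1.52 and 0.97. With the fraction labels of the pair labelled shHoxd13 exchanged, the planned shares of the arm labelled shHoxd13 were 40.1% (CD8 T-like), 25.7% (macrophage-like) and 1.86% (endothelial-like).

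At 500 UMIs in every library, the Ptprc share was 0.559% (shNTC, CD45-positive label) and 86.9% (shHoxd13, CD45-negative), macrophage-like cells were 29.6% of the latter, and fibroblast-like cells 92.5% and 66.9% of the libraries labelled shNTC CD45-negative and CD45-positive. At 1000 UMIs these were 91.5% for Ptprc (shHoxd13, CD45-negative) and 95.5% and 87.9% for fibroblast-like cells. Thinning to 500 UMIs, which itself removes UMIs, gave Ptprc shares of 0.00941% and 0.0101% (shNTC, CD45-negative and CD45-positive) and 37.8% (shHoxd13, CD45-negative). Thinned cells named by their own marker UMIs gave 4.99% macrophage-like and 84.3% keratinocyte-like cells (shHoxd13, CD45-positive). The Ptprc share there was 0.310% before thinning, so the 4.99% does not show macrophages. The same naming gave 10.4% CD8 T-like and 20.1% macrophage-like cells (shHoxd13, CD45-negative). It gave 0.235% endothelial-like and 70.3% fibroblast-like (shNTC, CD45-negative) and 65.7% fibroblast-like cells (shNTC, CD45-positive).

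With each fraction clustered on its own, CD8 T-like cells labelled shHoxd13 CD45-positive and macrophage-like cells labelled shNTC CD45-positive were 0%, and endothelial-like and fibroblast-like cells labelled shNTC CD45-negative 0.235% and 98.9%. Leiden resolution 0.5 gave 0% endothelial-like cells in both libraries labelled CD45-negative, 27.9% macrophage-like cells (shHoxd13, CD45-negative), and in fibroblast-like cells -0.29 for MHC class I, 0.66 for angiogenic ligands and -1.16 for interferon response. Without the highest Scrublet scores, keratinocyte-like cells were 95.2% (shHoxd13, CD45-positive) and their stress list 1.65. The mean of per-cell CPM gave 1.25 for that list. Centring moved MHC class I in fibroblast-like cells to -0.74.

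With the library labelled shNTC CD45-negative as reference, keratinocyte-like cells had -0.72 for MHC class I, -2.97 for cell cycle and 1.27 for stress, and fibroblast-like cells -0.94 for MHC class I. A 200-UMI filter gave -2.34 for cell cycle and turned chemokines to 0.26 in keratinocyte-like cells, and turned anti-angiogenic factors in fibroblast-like cells to -0.14, as did the 10-UMI expectation (-0.21), by leaving fewer genes. Without cluster 23s1, angiogenic ligands had -0.29, anti-angiogenic factors turned to -0.45 and Sema3a to 0.14. At this depth the 67 fibroblast-like cells labelled shHoxd13 CD45-positive, with a floor of 3.32 CPM, could not show Hoxd13 at the level of the other arm.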

Other observations

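No test was run in this part, and all of its values were chosen after they had been seen.

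The library labelled shHoxd13 CD45-negative held the immune cells of the series, and genes tied to vessel growth and immune restraint were spread over its classes in different ways. Vegfa, the main angiogenic growth factor, stood at 430 CPM (398 to 463) in NK-like cells, 304 CPM (293 to 316) in macrophage-like, 301 CPM (198 to 438) in neutrophil-like and 292 CPM (249.9 to 340) in monocyte-like cells, against 2.29 CPM (1.42 to 3.51) in CD8 T-like cells. Cd274, which encodes PD-L1, stood at 981 CPM (786 to 1208) in neutrophil-like, 837 CPM (741 to 943) in mature DC-like and 155 CPM (147 to 164) in CD8 T-like cells. Entpd1, the ectoenzyme that starts the breakdown of extracellular ATP toward adenosine, reached 2908 CPM (2566 to 3283) in neutrophil-like cells and 587 CPM (572 to 603) in macrophage-like cells. Nt5e, which completes that pathway, stood at 122 CPM (99.6 to 149) in T-like and 30.5 CPM (27.0 to 34.3) in CD8 T-like cells. The adenosine receptor gene Adora2a stood at 286 CPM (231 to 351) in mature DC-like, 211 CPM (181 to 244) in T-like and 87.5 CPM (81.5 to 93.8) in CD8 T-like cells. Cxcl9, a T cell attractant, stood at 529 CPM (472 to 592) in monocyte-like and 333 CPM (321 to 345) in macrophage-like cells, against 2.40 CPM (1.51 to 3.64) in CD8 T-like cells. The inflammatory cytokine gene Il1b stood at 5504 CPM (5030 to 6012) in neutrophil-like, 2200 CPM (2081 to 2324) in monocyte-like and 1045 CPM (1025 to 1067) in macrophage-like cells.

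Among lymphocytes of the same library, Tox, a factor of chronically stimulated T cells, stood at 1424 CPM (1371 to 1479) in gamma delta T-like, 1149 CPM (1052 to 1251) in regulatory T-like and 148 CPM (141 to 157) in CD8 T-like cells. The costimulatory receptor gene Tnfrsf9 stood at 1017 CPM (927 to 1114) in regulatory T-like and 248 CPM (238 to 258) in CD8 T-like cells, and Gzmb, which encodes granzyme B, at 199 CPM (160 to 244) and 159.7 CPM (152 to 168). The checkpoint gene Havcr2 stood at 204 CPM (195 to 214) in CD8 T-like and 131 CPM (100.2 to 169) in regulatory T-like cells. Nkg7, a cytotoxic granule gene, stood at 1218 CPM (1169 to 1269) in gamma delta T-like, 854 CPM (835 to 873) in CD8 T-like and 684 CPM (644 to 726) in NK-like cells. In the 60 endothelial-like cells of the library labelled shHoxd13 CD45-positive, the adhesion genes Icam1 and Vcam1 stood at 375 CPM (313 to 446) and 281 CPM (228 to 343), and the semaphorin and VEGF co-receptor gene Nrp1 at 635 CPM (554 to 726), against 94.2, 0.554 and 3.39 CPM in the keratinocyte-like cells around them.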
